A study of Mus musculus with 2 samples.

How the data were processed

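The series holds DNase-seq libraries from the lung of 4-day-old male mice of the strain B6CASTF1/J, an F1 cross of C57BL/6J and CAST/EiJ by its name. DNase-seq digests nuclei with the nuclease DNase I and sequences the ends of the fragments released, so that positions with many cuts mark accessible chromatin. Per the labels there were 2 biological replicates of 1 group, made from genomic DNA and processed on the mouse assembly mm10. The labels give the animals separate mouse numbers but a single donor entry, and nothing else in them says how far the tissues were independent. With 1 group there is no treated or control arm. The comparisons made were therefore replicate 1 against replicate 2, peaks against randomly placed peaks, gene lists against random gene lists, and sequence motifs against the same motifs reversed.

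Each library came with 2 peak lists, a list of footprints and a genome-wide file of false discovery rates for the cut rate. The deposited readme of each library states that these were made on mm10 from that library's own filtered alignments, and that footprints were made from the alignments and the cut rate file. The aligner, the peak and footprint callers, their versions and the read filters are not given in the sources used here. The authors gave each peak a signal value, a measure of coverage by cuts whose scaling is not stated. Within each library 100% of the deposited signal values under 1 were whole multiples of a single step, to within 0.05 of a step. The step was 0.00318 in replicate 1 and 0.00490 in replicate 2, a ratio of 1.54. If a step stands for the same number of cuts in both libraries, replicate 1 was sequenced 1.54 times as deeply, but the number of reads is not given in the sources used here. The authors' cut rate file holds a false discovery rate, a value of the q-value kind, per position and lists positions under 0.05. In both libraries every peak of the shorter deposited list holds a position under 0.001, and every peak of the longer list holds 1 under 0.05. The deposited footprints carry the constant 0.01, read as the p-value or false discovery rate threshold of the call and not as a value per footprint. Values of single peaks were used to describe and rank peaks within a library, and a ratio between libraries was always centred on its median.

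The shorter list of each library was the main peak list. The design asked for the narrower of both region files, and since widths were similar in both this was read as the list with fewer peaks. Peaks were counted as shared where they overlapped by at least 1 bp, and shares were set beside those of peaks moved to random places on their own chromosome. Shared peaks were joined in pairs for the correlation of signal. Coordinates are 1-based on mm10. The GRCm38.p6 sequence and the GENCODE M21 annotation supplied the genome and 21911 protein-coding genes on 21 chromosomes. A peak was called a promoter peak if its centre lay within 1 kb of a protein-coding transcription start site (TSS), and otherwise exonic, intronic or intergenic. Only protein-coding genes were used for this, so DNA called intergenic here can hold noncoding genes. Random places left out unsequenced bases. GC content was taken over 200 bp around each peak centre. For the GC correction the median log2 ratio of the libraries was found in 20 bins of GC content and removed from replicate 2.

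The 40 lists of marker genes were fixed with the tests, thresholds and motifs before the data were examined, namely 19 lists of lung cell types, 15 of cell types of other organs and 6 of cell states. They held 8 to 24 genes, and 1 gene symbol had no match in the annotation. Promoter accessibility was the share of a list's genes with a promoter peak in both libraries. Its percentile was taken among 10000 random lists of the same size from the same 10 classes of promoter GC content. Distal accessibility was the median number of peaks within 25 kb of the TSS and over 1 kb from every protein-coding TSS, with random lists drawn from the same 3 classes of gene density. Listed peaks of a library can overlap one another and were each counted, so numbers of peaks are not numbers of separate elements. A list was called high at the 97.5th percentile or above and low at the 2.5th or below, for distal peaks in both libraries. The difference between replicates was the median log2 ratio of summed signal within 25 kb after adding 0.1, with random lists drawn from the same 5 classes of mean signal. Genes are not replicates, so percentiles describe these 2 libraries and no p-value was computed across genes.

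For 41 consensus motifs, exact matches on both strands in peaks were scored as inside a footprint when at least 50% of the motif overlapped it. The share inside was compared with that of the reversed, not complemented, motif as a sample odds ratio with an exact conditional (Fisher) 95% interval. Fisher two-sided p-values were adjusted by Benjamini-Hochberg over the 27 motifs tested in each library. A motif was called when its interval excluded 1 on the same side in both libraries, and was not called with under 20 occurrences in either set. Intervals cover counting error only. Reversal keeps the base composition but not the neighbouring base pairs, and the GC box reads the same in reverse and so had no control.

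Genes were named by a rule. It took the 2 members with the most distal peaks from each list high in distal accessibility, with ties broken by summed signal. It took the first 2 of each list low in distal accessibility, and the 10 genes with the most distal peaks genome-wide, with ties broken likewise. It added 17 preset anchor genes and the 2 members with the largest change in the list's direction from each list that differed between the replicates. It also took the genes nearest the 5 strongest peaks of each library and the 5 strongest peaks found in a single library. Results for some of the genes are not reported here. Genes outside the rule are marked in the text as chosen after their values were seen.

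Alternatives included other overlaps, peak lists, promoter and gene windows, random lists matched otherwise or not at all, only the upper part of each list by signal, and leaving out each replicate. Added after seeing the data were the GC correction, lists without peaks under 0.3 signal, distal or promoter peaks alone, genes with peaks in both libraries, matching on GC in the difference, and footprints of 10 bp or more. The gene list statistics, the motif intervals and the overlap of peaks were tested on simulated data, and the other measures were not. Of 200 unchanged lists of 16 genes 1% were called high in distal accessibility, and 59% were called when the peak numbers were multiplied by 2. For promoters 4% of unchanged lists were called high and 1% low, against 98% called high when every closed promoter of a list was opened. Of unchanged lists 1.5% were called higher and 3% lower in replicate 2, against 89.5% called higher with a planted log2 shift of 0.5. For the 27 motifs the interval covered a planted odds ratio of 2 in 95.7% of draws. Such a ratio was called enriched in 72.2% of draws and a ratio of 1.5 in 45.2%, so weaker enrichment can be missed. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 20.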

Results

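Accessible chromatin was mapped by DNase-seq in lung tissue from male B6CASTF1/J mice at 4 days of age, when the alveoli begin to form. The data comprised 2 biological replicates of this single group, and pairs of values below give replicate 1 first. The shorter peak lists held 122280 and 154572 peaks, covering 24.4 and 29.9 Mb with median widths of 200 and 180 bp. The longer lists held 200736 and 230542 peaks. Median peak signal, in the authors' units, was 0.821 and 0.813. The strongest 10% of peaks carried 61.1% of the summed signal in replicate 1 and 49.1% in replicate 2. The number of reads behind these values is not given in the sources used here.

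Promoters of the main alveolar cell types, of endothelium and of mesenchyme were open in both lungs, whereas most promoters of blood cells and of other organs were not open in both. All 16 genes of the list for alveolar type 1 cells, the flat cells of gas exchange, had a promoter peak in both libraries, as did 15 of 16 genes of alveolar type 2 cells, which make surfactant. The same held for 18 of 18 genes of general epithelium, 17 of 18 of general endothelium and 14 of 14 of capillary endothelium. Among mesenchymal lists, 12 of 12 genes of smooth muscle and 22 of 24 of alveolar fibroblasts and myofibroblasts were open. These 7 lists stood at the 97.6th to the 99.9th percentile of random lists matched on promoter GC content. Across all protein-coding genes 65.8% were open in both libraries, 1023 genes were open in 1 library and 6463 in neither.

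Among lung cell types, 4 lists stood low. Only 6 of 20 genes of macrophages and monocytes were open in both libraries (percentile 0.020), 6 of 16 of B and T lymphocytes (0.415), 3 of 8 of airway basal cells (0.865) and 4 of 14 of erythroid cells and platelets (1.495). The remaining 8 lung lists were not called. They were airway secretory cells (7 of 12 genes open in both), ciliated cells (11 of 14), neuroendocrine cells (9 of 10), arterial and venous endothelium (10 of 12), lymphatic endothelium (5 of 8), pericytes (11 of 12), mesothelium (5 of 10), and neutrophils and mast cells (5 of 12). Of the 15 lists of other organs, 14 stood low, but 9 did without GC matching and 9 with a 2.5 kb window. Open in both libraries were 1 of 16 genes of hepatocytes, 2 of 14 of skeletal muscle, 7 of 16 of cardiomyocytes, 3 of 12 of intestinal epithelium, 3 of 14 of pancreas and 3 of 12 of kidney epithelium. The counts were 9 of 16 for neurons, 5 of 12 for astrocytes and oligodendrocytes, 2 of 10 for photoreceptors and lens, 1 of 12 for testis germ cells and 4 of 12 for pluripotent cells. They were 4 of 10 for brown and white adipocytes, 1 of 12 for keratinocytes, and 6 of 13 for genes that pattern body regions outside the lung. Thymocytes, with 3 of 8 genes open, were not called (percentile 20.4). Among cell states, all 20 genes of the cell cycle list and all 20 ribosomal protein genes were open, at percentiles 99.8 and 99.3. The lists for the immediate early and stress response (19 of 19), the interferon response (11 of 15), glucocorticoid and circadian targets (16 of 16) and developmental signalling (21 of 22) were not called, but without GC matching all of these except the interferon response were high.

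Where few genes of a list were open, or few closed, genes named here were chosen after their values were seen. In hepatocytes the open gene was Apob, for apolipoprotein B, with a promoter signal of 0.840 and 2.10. In keratinocytes it was Krt10 (13.5 and 7.94), in testis germ cells Dazl (11.4 and 9.20), in skeletal muscle Mylpf (16.8 and 10.4) and Casq1 (2.60 and 4.24), and among photoreceptor and lens genes Opn1sw (10.9 and 6.80) and Cryab (8.65 and 5.15), a small heat shock protein gene. The open genes of pancreas were Ptf1a, Cela1 and Nkx6-1, those of intestinal epithelium included Vil1 and Lgr5, and those of kidney epithelium included Lhx1 and Cdh16. Pluripotent cells had Pou5f1, Esrrb, Utf1 and Sox2, which the list of general epithelium also holds, adipocytes Cidea, Prdm16, Plin1 and Ppargc1a, and glia Slc1a2, Slc1a3, Olig1, Mbp and Aldh1l1. Among lung lists, basal cells had Ngfr, Aqp3 and Icam1, and the open genes of erythroid cells and platelets included Pf4, Gp9 and Tfrc, the transferrin receptor gene, at 18.7 and 9.76. Of the lists not called, the open genes included Cd1d1 and Themis for thymocytes, while lymphatic endothelium had Prox1, Lyve1, Flt4, Reln and Pdpn, mesothelium Upk1b, Krt19, Aldh1a2, Cpe and C3, and neutrophils and mast cells S100a8, Csf3r, Mpo, Camp and Gata2. In the high lists of lung cell types, the genes not open in both libraries were Lamp3 for alveolar type 2 cells, Emcn for general endothelium, and Lum and Inmt for fibroblasts.

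Several of these calls needed both libraries. A call could also be gained, as 3 state lists were high with replicate 2 alone, against 2 with both libraries. With either library alone, alveolar type 1 cells (percentiles 96.4 and 96.5) and general epithelium (96.4 and 96.4) were no longer high, although all of their promoters were open, and the same held with the longer lists and with a 2.5 kb window. In the upper part of each list by signal, alveolar type 1 cells fell to percentile 84.8, fibroblasts to 94.6 and smooth muscle to 96.7. General endothelium was at 97.2 with the 2.5 kb window. Among other organs, neurons and the patterning genes were not low in replicate 1 alone, nor were pancreas, glia, adipocytes and pluripotent cells in replicate 2 alone. With replicate 2 alone the list of pluripotent cells was at percentile 50.7, with 9 of 12 promoters open, and macrophages and monocytes were at 15.3, with 12 of 20 open. In each library taken alone 2 lung lists were low, which were airway basal cells and B and T lymphocytes in replicate 2, and macrophages and monocytes and erythroid cells and platelets in replicate 1.

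Distal peaks were numerous around genes of endothelium and of fibroblasts and, unless GC content was matched, of airway and alveolar type 1 epithelium. Genes of general endothelium had a median of 7.0 and 6.5 distal peaks within 25 kb of the TSS, and those of airway secretory cells, which line the conducting airways, 6.0 and 5.5. Medians were 4.5 and 7.0 for general epithelium, 5.0 and 6.0 for capillary endothelium, 5.0 and 5.0 for arterial and venous endothelium, 4.5 and 5.0 for alveolar type 1 cells, and 4.0 and 5.0 for alveolar fibroblasts and myofibroblasts. Random lists had medians of 1 to 1.5 peaks in replicate 1 and of 2.5 to 3 in replicate 2 for these sets. These 7 lung lists were at or above the preset limit in both libraries, and the lowest of their values was 97.7, for arterial and venous endothelium in replicate 2. With random lists matched on the GC content of the window, 3 lung lists stayed high, namely general endothelium, capillary endothelium and alveolar fibroblasts and myofibroblasts. None of the 15 lists of other organs was called, with medians of 1 to 3.5 peaks in replicate 1 and 2 to 4.5 in replicate 2.

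The genes with the most distal peaks in each of these lists included well-known regulators and products of the lung. Aqp5 (15:99590782-99594829), the water channel of alveolar type 1 cells, had 9 and 13 distal peaks, and Hopx (5:77086988-77115121), a homeodomain protein of the same cells, had 10 and 11. Scgb1a1 (19:9083636-9087958), which encodes the secretory protein of club cells, had 10 and 13 distal peaks and no promoter peak in either library. Hp (8:109575128-109579172), for haptoglobin, had 21 and 6, but without peaks under 0.3 signal 3 and 6. Cldn3 (5:134986214-134987472), a tight junction gene, had 13 and 12, and Krt8 (15:101996698-102004482), a keratin of simple epithelia, 12 and 10. In endothelium, Egfl7 (2:26580014-26593120) had 12 and 13, Cdh5 (8:104101625-104144511), for the cadherin of endothelial junctions, 14 and 9 (8 and 9 without peaks under 0.3 signal), and Plvap (8:71497765-71511752), for a protein of capillary diaphragms, 17 and 13. The arterial Notch ligand gene Dll4 (2:119325784-119335962) had 16 and 12, and the venous regulator Nr2f2 (7:70351944-70366735) had 10 and 13. Tbx2 (11:85832551-85841948), which encodes a T-box transcription factor, had 27 and 29 distal peaks, a mean of 28.0 ± 1.41 (SD, n = 2). In the fibroblast list, the elastin gene Eln (5:134702593-134747323) had 18 and 11, and 11 and 11 without these weak peaks. Tbx5 (5:119832668-119885219) had 25 and 4, and 16 and 4 without peaks under 0.3 signal.

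**Figure D1:**
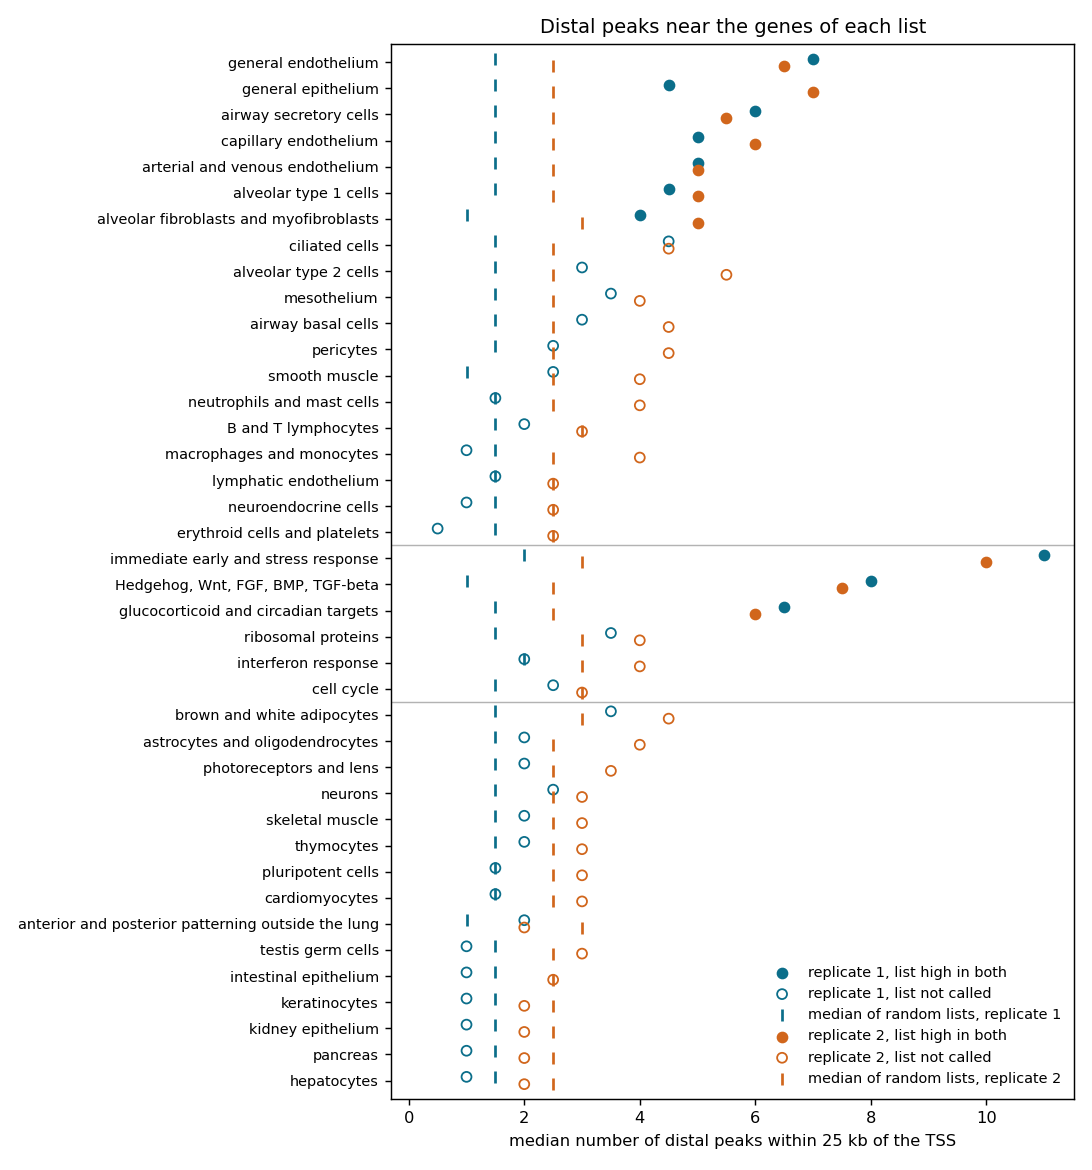
Median number of distal peaks within 25 kb of the TSS (horizontal axis, number of peaks) for each of the 40 gene lists, as 1 point per library, with vertical marks for the median of random lists. Filled points are the 10 lists high in both libraries, of which the immediate early and stress response list was highest, at 11 and 10 peaks.

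Lists of cell states also stood high in distal peaks. Immediate early and stress response genes had a median of 11 and 10 distal peaks, developmental signalling genes of the Hedgehog, Wnt, FGF, BMP and TGF-beta pathways 8.0 and 7.5, and glucocorticoid and circadian targets 6.5 and 6.0. Nr4a1 (15:101254269-101274795), an immediate early nuclear receptor gene, had 34 and 21 distal peaks, and Btg2 (1:134075170-134079120) had 24 and 18. Without peaks under 0.3 signal these were 24 and 21 for Nr4a1 and 19 and 18 for Btg2. The clock genes Per1 (11:69095217-69109960) and Nr1d1 (11:98767932-98775333) had 17 and 26, and 23 and 19, and Per1 had 11 and 15 without peaks under 0.3 signal. Smad7 (18:75367529-75395935), an inhibitor of TGF-beta signalling, had 21 and 18. Shh (5:28456815-28467256), the Hedgehog ligand gene of the airway epithelium, had 22 and 15, or 15 and 14 without peaks under 0.3 signal. Its promoter was listed with no peak in replicate 1 and had a signal of 0.470 in replicate 2.

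Some lung cell types were not called high. Alveolar type 2 genes had medians of 3.0 and 5.5 (percentiles 92.7 and 99.8) and ciliated genes 4.5 and 4.5 (99.4 and 95.9), so each passed in a single library. Also not called were airway basal cells (3.0 and 4.5), neuroendocrine cells (1.0 and 2.5), lymphatic endothelium (1.5 and 2.5), smooth muscle (2.5 and 4.0), pericytes (2.5 and 4.5) and mesothelium (3.5 and 4.0). The same held for macrophages and monocytes (1.0 and 4.0), neutrophils and mast cells (1.5 and 4.0), B and T lymphocytes (2.0 and 3.0), erythroid cells and platelets (0.5 and 2.5), the cell cycle (2.5 and 3.0), ribosomal proteins (3.5 and 4.0) and the interferon response (2.0 and 4.0). General endothelium and the fibroblast list were high in each alternative run, and the other 5 lung lists each lost the call in at least 1. Without peaks under 0.3 signal the arterial and venous list was no longer high, with a median of 2.5 in replicate 1.

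The preset anchor genes separated lung regulators from genes of other organs. Nkx2-1 (12:56531958-56536908), the master regulator of lung epithelium, had a promoter signal of 5.85 and 2.84 and 10 and 9 distal peaks. Sftpc (14:70520949-70524081), for surfactant protein C, had a promoter signal of 6.96 and 3.01 and 28 and 13 distal peaks, or 23 and 13 without peaks under 0.3 signal. Foxf1 (8:121084386-121088144), a forkhead gene of lung mesenchyme and endothelium, had 8.58 and 4.37 with 10 and 17 distal peaks. The mesenchymal regulator Tbx4 (11:85886422-85916097) had 3.91 and 2.54, and Foxj1 (11:116330704-116335399), which drives the formation of motile cilia, 15.5 and 12.1. The myeloid regulator Spi1 (2:91082390-91115756) had 3.67 and 2.75, and the endothelial gene Pecam1 (11:106654217-106750628) had 0.933 and 1.31. Wt1 (2:105126529-105173616), a gene of the mesothelium, had a promoter signal of 0.770 in replicate 1 and was listed with no promoter peak in replicate 2. Of the anchors from other organs, the cardiac myosin gene Myh6, the muscle regulator Myod1 and the recombinase gene Rag1 of lymphocytes were listed with no promoter peak in either library. The albumin gene Alb had 0.206 in replicate 2 alone. The pluripotency gene Pou5f1 (17:35506018-35510772) was the exception, with 1.19 and 1.56.

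Peaks lay at promoters far more often than chance placement gives. In the genomic location of peaks, 21.8% and 19.4% fell within 1 kb of a protein-coding TSS, a mean of 20.6% ± 1.73 (SD, n = 2), against 2.71% and 2.62% of random places. Exons held 7.05% and 4.42% of peaks (random 3.29% and 3.34%), introns 35.5% and 36.8% (random 36.5% and 36.4%) and intergenic DNA 35.6% and 39.4% (random 57.5% and 57.7%). The strongest peak of both libraries was at the promoter of the dynein light chain gene Dynlt1b (17:6430001-6430180), with a signal of 112 and 62.3. Next in replicate 1 were peaks at the promoters of Mxd1 (6:86669241-86669560, 78.7 and 27.2), Bahcc1 (11:120232701-120232900, 77.3 and 31.5) and Dnpep (1:75317521-75317780, 76.3 and 34.6), and in an intron near Gm21887 (X:169997961-169998240, 73.8 and 38.4). In replicate 2, the next peaks were at Trpm8 (1:88277541-88277760, 69.4 and 53.4) and in intergenic DNA nearest to Esp38 (17:39846781-39846920, 32.2 and 44.2) and to Pak3 (X:143482981-143483140, 2.31 and 40.9), followed by the Gm21887 peak. Peaks in repeated or multicopy sequence were not filtered out here, and whether reads from such sequence raised any of these peaks was not examined.

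The X chromosome, which is single in male cells, carried fewer peaks than the autosomes, with a lower median signal. For the X chromosome signal, the median peak was 0.657 and 0.505, against autosome medians that ranged from 0.758 to 0.914 and from 0.730 to 0.980 over the 19 autosomes. The ratio to the median autosome was 0.800 and 0.613, a mean of 0.707 ± 0.132 (SD, n = 2). Peak density on X was 14.2 and 23.4 peaks per Mb, under the lowest autosome at 33.2 and 49.7. In the upper part of each list by signal, a choice that itself narrows the range of signal, the ratio was 1.17 and 0.986. The Y chromosome held 80 and 41 peaks.

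The replicates shared most of their strong peaks and few of their weak ones. Among shared peaks, 70.5% of the list of replicate 1 overlapped a peak of replicate 2, and 55.9% of the list of replicate 2 overlapped a peak of replicate 1, a mean of 63.2% ± 10.3 (SD, n = 2). Random placement gave 2.47% and 1.95%. Of the strongest signal quintile, 99.5% and 94.5% of peaks were shared, and of the weakest 4.10% and 13.7%. Promoter peaks were shared at 87.4% and 78.5% and distal peaks at 65.8% and 50.5%. Taking the same number of strongest peaks from each library gave 66.9% and 67.0%.

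Peak signal was ranked alike in both lungs, most closely at promoters. The peak signal between replicates had a Spearman correlation of 0.836 across 85200 shared pairs of peaks, from 0.807 to 0.852 on single autosomes, and a Pearson correlation of 0.886 on the log2 scale. Peaks are not independent replicates, and the correlation is across peaks of 2 libraries. It was 0.962 across 22917 promoter pairs and 0.749 across 62283 distal pairs. After centring, the log2 ratio had an SD of 0.73 and 15.4% of the pairs differed by more than 2-fold.

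**Figure D2:**
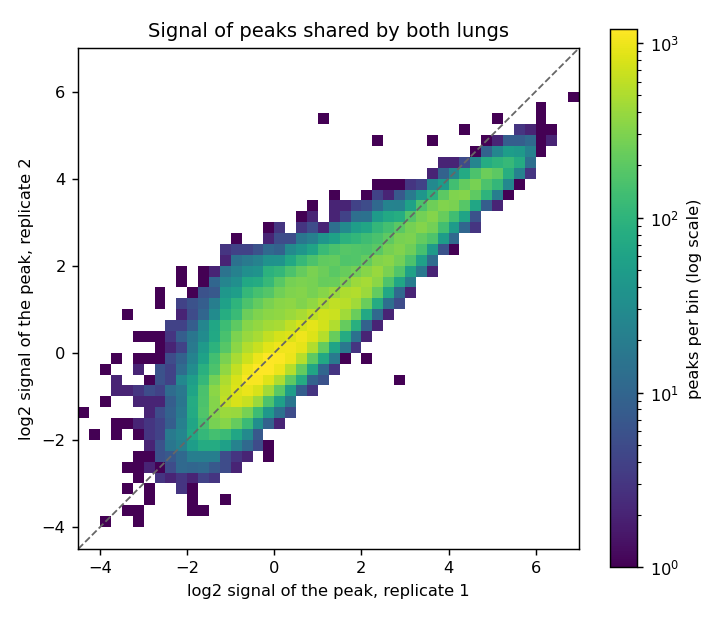
Log2 signal of each shared peak in replicate 1 (horizontal axis) and in replicate 2 (vertical axis), as a density of 85200 pairs with the number of peaks per bin on a log colour scale and a dashed line of equality. Signal followed a slope of 0.869 on the log2 scale, so that the strongest peaks tended to be lower in replicate 2, in units whose scaling is not stated. After the GC correction the slope was 0.983.

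The ratio of the libraries moved with base composition. In the GC-poorest quintile of shared peaks, with a median GC content of 47.5%, the centred log2 ratio of replicate 2 over replicate 1 was 0.61, and in the GC-richest quintile, at 69%, it was -0.39. Distal peaks ran from 0.66 to -0.26 and promoter peaks from 0.23 to -0.49. The lists themselves differed in the same way, with a median GC content of 54.5% and 51.0%. Removing the trend raised the Spearman correlation to 0.882 and lowered the share of pairs that differed by more than 2-fold to 10.9%. It also moved the slope of replicate 2 on replicate 1, on the log2 scale, from 0.869 to 0.983.

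**Figure D3:**
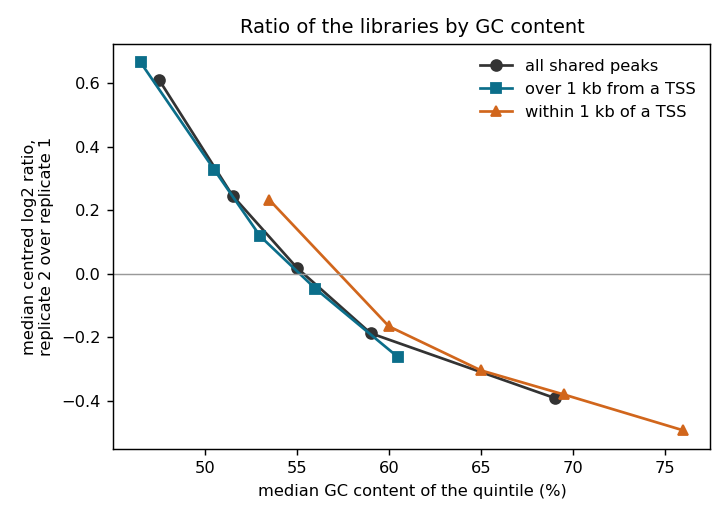
Median centred log2 ratio of signal, replicate 2 over replicate 1 (vertical axis), against the median GC content of each quintile of shared peaks in percent (horizontal axis), for all, distal and promoter peaks. The ratio falls with GC content in each set, from 0.61 to -0.39 over all shared peaks.

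Peaks in one library alone were mostly weak. Replicate 1 had 28928 peaks with no overlap in either list of replicate 2, 23.7% of its list, with a median signal of 0.166. Replicate 2 had 45896 such peaks, 29.7%, with a median of 0.456, and the mean share was 26.7% ± 4.27 (SD, n = 2). Only 34 and 194 of them exceeded the 90th percentile of their list. The strongest in replicate 1 were at the promoters of Sf1 (19:6363341-6363423, signal 31.9), Wipi1 (11:109611741-109612040, 29.3), Atl2 (17:79896121-79896220, 15.99) and Hinfp (9:44305997-44306060, 12.6, and 9:44305601-44305639, 12.4). In replicate 2 they were at Sf1 (19:6363481-6363900, 22.6), Hinfp (9:44305661-44305980, 17.2), Tbl2 (5:135148961-135149260, 14.8), intergenic DNA nearest to Pcmtd1 (1:7397861-7398040, 12.4) and Tmem143 (7:45896941-45897120, 11.4). At Sf1 and Hinfp the listed peaks of the libraries were neighbouring segments of the same promoter, so these promoters were open in both lungs.

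The 10 genes with the most distal peaks genome-wide were led by replicate 1. The predicted gene Gm6588 (5:112449426-112451738) had 71 and 8 distal peaks, Rassf2 (2:131989415-132030258) 68 and 9, the splicing factor gene Sf1 (19:6363690-6378030) 58 and 5, and Fam213b (4:154895504-154899135) 54 and 6. The neighbours Sema3g and Nisch on chromosome 14 had 54 and 14, and 53 and 14. Zfp36l2 had 50 and 16, the kinase gene Sik1 48 and 13, Zmiz1 46 and 19, and Trim8 43 and 22. For these genes other than Trim8, most of the excess lay in peaks under 0.3 signal, of which replicate 1 had 24776 (20.3% of its list) and replicate 2 14045 (9.09%). Without them Gm6588 had 8 and 8 distal peaks, Rassf2 11 and 9, Sf1 12 and 5, Fam213b 8 and 6, Sema3g and Nisch 22 and 14 each, Zfp36l2 15 and 14, Sik1 16 and 13, Zmiz1 20 and 19, and Trim8 36 and 22. Trim8 alone of these genes was then still among the 10 highest, which included Bahcc1 (20 and 36) and Rara (36 and 20), both named after their values were seen. In the 50 kb around the Gm6588 TSS, inside the gene Sez6l, 67 of 75 peaks of replicate 1 were under 0.3, against 0 of 8 in replicate 2. Around Sftpc the figures were 5 of 37 and 0 of 22.

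**Figure D4:**
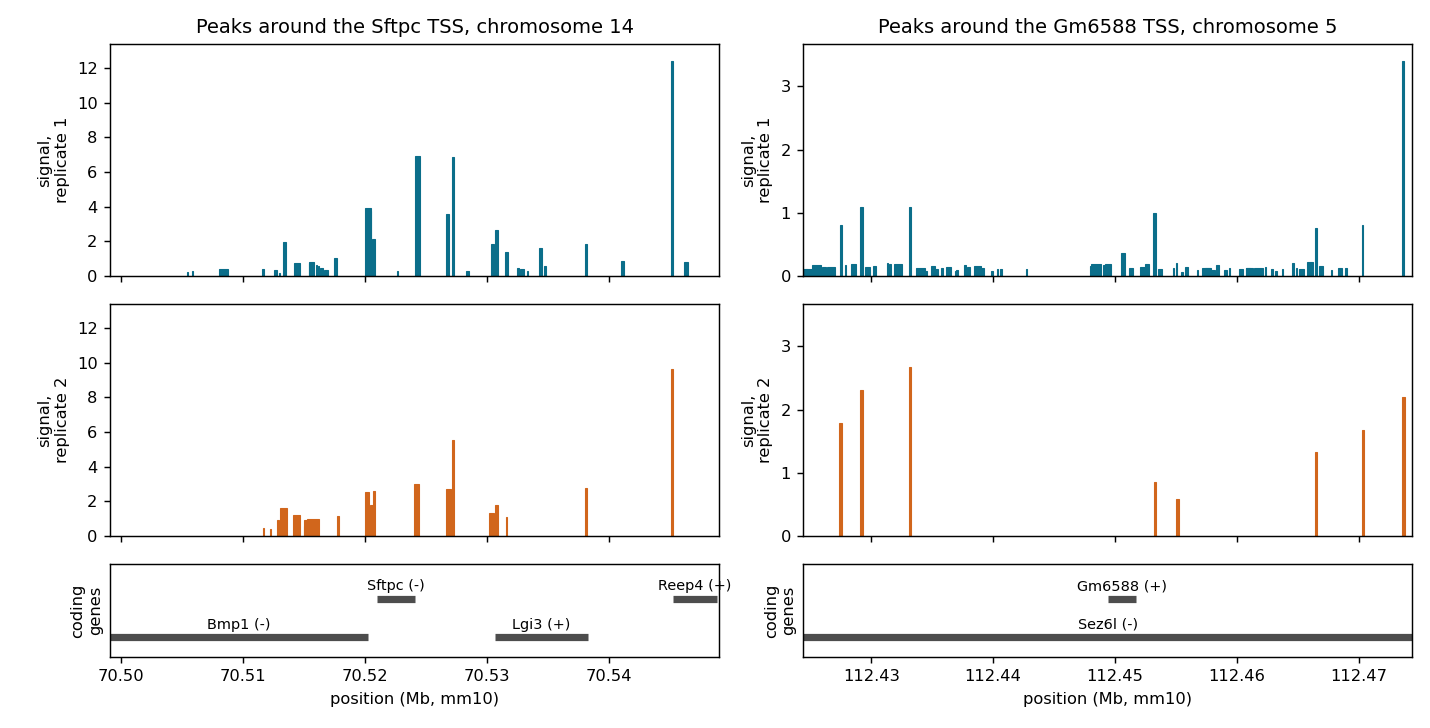
Peaks of the shorter lists within 25 kb of the Sftpc TSS (left) and of the Gm6588 TSS (right), with the signal of each peak on the vertical axes, on a different scale for each region, position on mm10 in Mb on the horizontal axes, and protein-coding genes drawn underneath with their strand. Around Sftpc the libraries have 37 and 22 peaks, and around Gm6588 75 and 8.

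Genes of 6 lists carried more summed signal of called peaks in replicate 2 than matched random lists, relative to all genes, but on peaks found in both lungs ciliated cells alone of the 6 were called, at 0.42 and percentile 99.8. A peak that was not called adds nothing to a sum, and the lists cover 24.4 and 29.9 Mb with median signals of 0.821 and 0.813, so the sums also move with how much was called in each library. Ratios are of summed signal plus 0.1, centred on all protein-coding genes, which understates the change of genes with little signal. The median log2 ratio was 1.34 for thymocytes (6 of 8 genes higher, percentile 99.9), 1.23 for erythroid cells and platelets (8 of 13, percentile 99.8), 1.14 for macrophages and monocytes (17 of 20, percentile 98.3), 0.39 for alveolar fibroblasts and myofibroblasts (14 of 24, percentile 99.4), 0.34 for ciliated cells (10 of 13, percentile 99.5) and 0.04 for ribosomal proteins (11 of 20, percentile 99.9). Random lists matched to the ribosomal genes had medians from -0.38 to -0.06. No list was higher in replicate 1, and the other 34 lists were not called. Several leading members were listed with no peak within 25 kb in replicate 1 and so have no fold. These were the complement gene C1qa and the scavenger receptor gene Marco of macrophages, the red cell membrane genes Epb42 and Slc4a1, Cd8b1 of thymocytes, and the growth factor gene Fgf10 of fibroblasts around its main TSS, although a promoter peak at another TSS of Fgf10 had 0.783 and 0.554. Their summed signal in replicate 2 was 3.03, 0.764, 1.48, 1.00, 1.00 and 0.652. Rag2, of the recombinase, had 2.31 and 8.12. For ciliated cells the dynein gene Dnah5 had 1.23 and 4.86 and Pifo 1.076 and 2.67. The matrix gene Dcn had 0.283 and 1.77, Rpl5 11.5 and 15.03 and Rpl11 16.4 and 19.8.

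These calls rest on 1 library against 1 and changed with the choice of peaks. With distal peaks alone none of the 6 lists was called, and 3 lists were higher in replicate 1, namely general endothelium, keratinocytes and developmental signalling. After the GC correction ciliated cells (0.24, percentile 99.2) and erythroid cells (0.64, percentile 98.4) stayed above the limit, while macrophages (0.71, percentile 97.1), thymocytes (0.66, percentile 95.4), fibroblasts (0.18, percentile 90.3) and ribosomal proteins (-0.08, percentile 84.5) did not. The erythroid list was at percentile 43.9 in a 50 kb window and on distal peaks, and at 18.0 in genes with a peak in both libraries. In a 50 kb window ciliated cells were at 0.22 and percentile 96.5, and not called.

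Footprints, short stretches inside accessible DNA that are protected from cutting, numbered 508977 and 559396 with a median width of 10 bp. Of these, 63.1% and 74.0% lay in the shorter peak lists, where 84.1% and 88.8% of peaks held at least 1. Footprints overlapped a footprint of the other library at 45.4% and 41.9%, a mean of 43.6% ± 2.49 (SD, n = 2). Within peaks the shares were 54.6% and 46.3%, against 39.2% and 32.7% for footprints moved at random within the peaks.

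Of 20 tested motifs preset as those of lung regulators, 7 lay in footprints more often than their reversed forms, 12 were not called and 1 was depleted. The motif of NKX2 factors, which include the lung regulator NKX2-1, was in a footprint at 30.7% and 40.6% of its sites, against 10.9% and 13.04% for the reversed motif. Its odds ratios were 3.64 (95% interval 2.68 to 5.00) and 4.56 (3.55 to 5.91), with a Fisher adjusted p of at most 2.38e-19. Odds ratios were 6.85 and 5.80 for ETS factors, 2.95 and 3.51 for a single arm of the palindrome of nuclear factor I (NFI), 12.4 and 11.9 for C/EBP factors, 3.74 and 2.72 for SOX factors, 2.05 and 1.49 for TEAD factors and 1.76 and 1.72 for RUNX factors. HNF4, preset as a factor of other organs, had 3.81 and 1.97. The widely used motifs were also enriched, at 2.40 and 1.94 for the CCAAT box of NFY, 20.4 and 29.6 for the cyclic AMP response element (CRE) and 8.72 and 12.97 for the USF E-box. These were the 11 enriched motifs, and over them the largest Fisher adjusted p in either library was 0.0114, for HNF4. The SMAD motif was depleted, at 0.574 and 0.563, with a Fisher adjusted p of at most 0.0442. The SMAD call was lost in distal peaks (mean odds ratio 0.635, Fisher adjusted p = 0.144), with the whole motif in the footprint (0.649, Fisher adjusted p = 0.634) and with footprints of 10 bp or more (0.595, Fisher adjusted p = 0.133), at ratios near the mean of 0.569, and was kept against all peak bases (0.469). TEAD, with a mean odds ratio of 1.77, was not called with the whole motif (1.42), with these footprints (1.83) or against all peak bases (1.01). HNF4, with a mean of 2.89, was not called with the whole motif (3.11) or against all peak bases (1.05), and RUNX not against all peak bases (0.885). In distal peaks C/EBP had too few control sites to be called. Calls were kept at smaller ratios against all peak bases for NKX2 (1.73 and 2.62), SOX (1.24 and 1.15) and NFY (1.42 and 1.37) and in distal peaks for ETS (2.54 and 2.25) and CRE (9.73 and 17.6). They were kept at larger ones with the whole motif for C/EBP (28.9 and 43.1) and USF (23.1 and 19.8), and for USF against all peak bases (16.4 and 17.0).

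**Figure D5:**
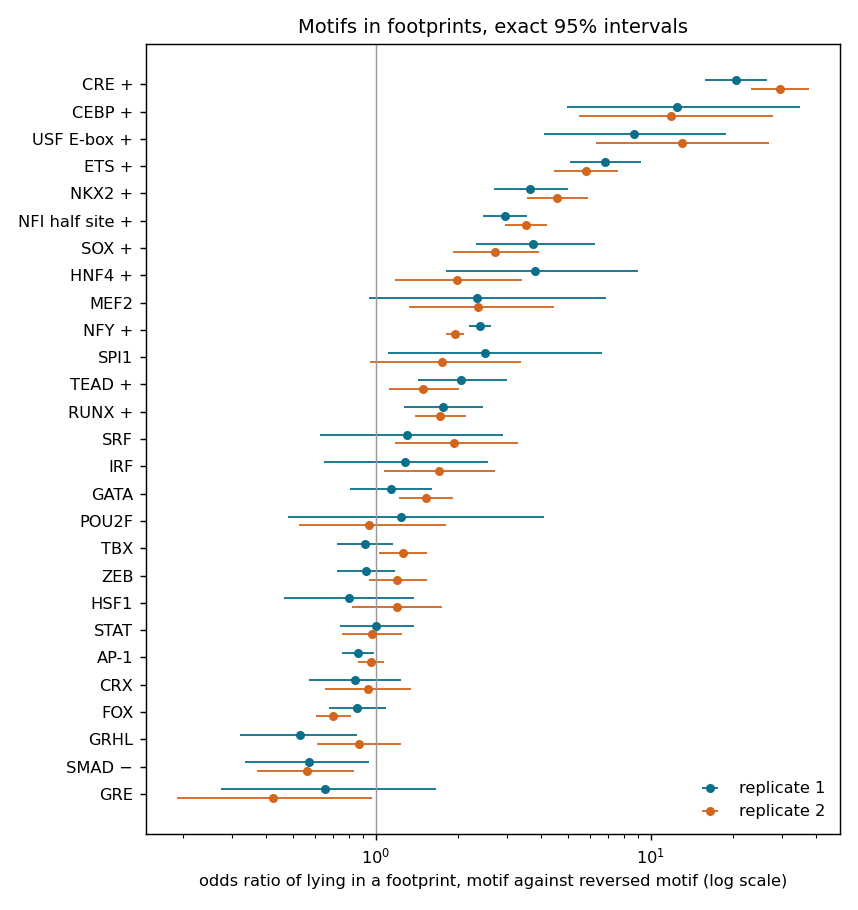
Odds ratio of lying in a footprint for each of the 27 tested motifs against the same motif reversed (horizontal axis, log scale), with exact 95% intervals for each library. A plus sign marks the 11 motifs called enriched in both libraries and a minus sign the 1 called depleted, and CRE has the largest ratios at 20.4 and 29.6.

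The other 15 tested motifs were not called. Among them were forkhead (FOX, 0.859 and 0.701), AP-1 (0.864 and 0.962), GATA (1.14 and 1.52), T-box (TBX, 0.916 and 1.26), SRF (1.30 and 1.93), MEF2 (2.33 and 2.36), PU.1 (SPI1, 2.51 and 1.74), grainyhead-like (GRHL, 0.530 and 0.873), interferon regulatory (IRF, 1.28 and 1.69) and glucocorticoid receptor (GRE, 0.655 and 0.424) motifs. The rest were STAT (1.01 and 0.966), ZEB (0.920 and 1.1997), CRX (0.841 and 0.937), the octamer of POU2F (1.24 and 0.943) and HSF1 (0.799 and 1.19). With the whole motif in the footprint, AP-1 (mean odds ratio 1.36) and STAT (1.58) were called enriched and GRHL (0.571) depleted, although their Fisher adjusted p reached 0.0600, 0.0870 and 0.0697. Against all peak bases AP-1, STAT, FOX, GATA, GRE, ZEB, CRX, POU2F and HSF1 were called depleted. A further 14 motifs had too few control sites or no distinct reversed form. Of these, CTCF, the insulator protein, had 95.9% and 95.7% of its 3767 and 6863 sites in footprints, NRF1 96.0% and 96.7%, the repressor REST 93.0% and 96.1%, and the full NFI motif 93.0% and 90.9%. The GC box had 80.8% and 75.9%, YY1 53.8% and 50.9%, and the myogenic E-box (MYOD) 26.3% and 25.9%, beside 18.6% and 18.8% of all peak bases. The E-box of TCF21 had 20.8% and 34.6%. The RFX motif of ciliated cells had 17 of 18 and 20 of 24 sites in footprints. The motifs of COUP, HNF1, PAX6, p53 and the POU5F1-SOX2 pair each had at most 17 sites. The intervals cover counting error only, and some reversed motifs resemble sites of other factors, so a ratio near or below 1 does not show that a factor was absent.

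The cut rate calls showed how much of the genome each library marked. Positions under a false discovery rate of 0.05 covered 63.9 and 73.7 Mb, a mean of 68.8 Mb ± 6.91 (SD, n = 2), and those under 0.001 covered 40.7 and 48.0 Mb. Of the length under 0.05, 67.3% and 58.4% was also marked in the other library. The shorter peak lists held 59.4% and 61.7% of the length under 0.001.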

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

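The GC correction, the settings without peaks under 0.3 signal, with distal or promoter peaks alone, with peaks in both libraries, with GC matching in the difference and with wider footprints, and some uses of the longer or shared lists, were chosen after the results were seen. No paired analysis was possible because there was 1 group. A threshold on the footprint score was planned for footprints and for motifs and not run, since the score is a constant. The peak signal between replicates, the difference between replicates and the peaks in one library alone need both libraries, so no replicate could be left out of them. The number of reads is not given in the sources used here, so the limits set by depth are unknown. The cause of a change below was not tested unless the setting itself makes it.

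Keeping the upper part of each list by signal gave 78.9% shared peaks, a Spearman correlation of 0.805, 30.9% promoter peaks and a ratio to the autosomes of 1.077 for the X chromosome signal (1.17 and 0.986 by library). It also gave 4 lung lists and 4 state lists high at promoters, 3 lists higher in replicate 2 and 1 in replicate 1. The longer lists gave 15.7% promoter peaks, an X ratio of 0.552, 2 lung lists low at promoters and 1 list higher in replicate 1. A promoter window of 2.5 kb gave 26.9% promoter peaks by construction, 2 lung lists low and 9 lists of other organs low. Shared peaks gave 27.1% at promoters, 2 lists higher in replicate 2 and 1 in replicate 1. Promoter peaks alone gave an X ratio of 0.563, 2 lists higher in each replicate, and distal peaks alone 0 lists higher in replicate 2 and 3 in replicate 1. The GC correction gave a correlation of 0.882, 3 lists higher in replicate 2 and 2 in replicate 1. Without matching, 9 lists of other organs were low and 5 state lists high at promoters. For distal peaks, 4 lung lists were high in a 10 kb window and 3 with GC matching. Shared footprints were 30.5% with a reciprocal overlap of 50% and 50.5% at widths of 10 bp or more. The cut rate calls covered 55.3 Mb at 0.01 and 44.3 Mb at 0.001. Peaks in one library alone were 36.8% against the shorter list of the other library. With all peak bases as control 10 motifs were depleted, and 0 with distal peaks or wider footprints.

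Leaving out each replicate gave 2 lung lists low at promoters either way, 3 depleted motifs either way, and for the promoters of pluripotent cells percentiles of 0.115 and 50.7, which crosses the middle of the random lists. Single results that changed direction were the fibroblast difference (percentile 41.7 in the upper lists, 48.5 on shared peaks, 6.22 on promoter peaks), the erythroid difference (43.9 at 50 kb, 18.0 in genes with peaks in both libraries, 43.9 on distal peaks), thymocytes on promoter peaks (21.3) and ribosomal proteins on distal peaks (27.6). With the whole motif in the footprint, AP-1 had an odds ratio of 1.36 and STAT 1.58, both called. Against all peak bases, GATA had 0.510, RUNX 0.885, ZEB 0.656 and POU2F 0.568. Over all lists and settings, the call or its absence was kept in 343 of 395 values for the difference, 407 of 440 for distal peaks and 228 of 280 for promoters. For motifs it was kept in 128 of 159. For the difference and distal peaks most lists were not called, so these shares mostly count lists that stayed uncalled. Beside the changes of direction, a call was lost in 22 values for the difference, 19 for distal peaks, 41 for promoters and 8 for motifs. For the difference, all 8 changes of direction were also in called lists. Of 392 values of named genes, 113 moved by more than their SD. The 392 include values with a replicate left out, which cannot lie over 1 SD from a mean of 2. They therefore understate how often values moved in the other settings. Some of those settings change the window and so the number of peaks by construction.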

Other observations

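Tests chosen after the results were seen were those of spread around open regions and of airway epithelium, the GC content of weak peaks, and the settings with GC matching, GC correction, or distal or promoter peaks alone, and the Hox and Y-linked genes were also picked then. The rules for RFX sites, for scaling of promoter peaks and for GC-dependent recovery of weak peaks were made stricter after the values were seen. By the rules first written, the values counted against RFX sites and for the other 2 explanations. The homeobox genes of the Hox clusters, which mark position along the body axis, differed by cluster. In the HoxA cluster on chromosome 6, Hoxa2, Hoxa3, Hoxa4, Hoxa5, Hoxa6 and Hoxa7 had a promoter peak in both libraries. In the HoxB cluster on chromosome 11, 6 of 7 genes of paralogue groups 1 to 7 did, all but Hoxb1. Hoxc4, Hoxc5 and Hoxc6 in the HoxC cluster on chromosome 15, and Hoxd1, Hoxd3 and Hoxd4 in the HoxD cluster on chromosome 2, were not open in both. Signal was 9.88 and 6.93 at Hoxa4, 7.95 and 7.59 at Hoxa5, and 7.60 and 6.47 at Hoxb5. Of groups 8 to 13, 5 of 19 genes were open in both libraries. The 5 were Hoxa10 (3.43 and 4.56), Hoxc10 (1.40 and 2.46), Hoxc13 (0.952 and 0.960), Hoxd8 (0.818 and 0.549) and Hoxd10 (1.81 and 1.18). Distal peaks in the HoxA cluster differed between the lungs, with 39 and 2 around Hoxa7.

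On the Y chromosome, 4 of 183 protein-coding genes had a promoter peak in both libraries. They are partners of X-linked genes that are active in many tissues. Promoter signal was 3.30 and 3.60 at the RNA helicase gene Ddx3y (Y:1260771-1286629), 2.38 and 3.29 at the translation factor gene Eif2s3y (Y:1010543-1028847), 1.05 and 3.13 at Uty (Y:1096861-1245759) and 1.499 and 1.94 at the histone demethylase gene Kdm5d (Y:897788-956786).

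Replicate 1 held 24776 peaks under 0.3 signal, which crowd around genes such as Gm6588 and Rassf2. If they were sites that only a deeper library can call, the same places should nearly pass in replicate 2, but 8.64% of them held a position listed there under 0.05, and 10.1% did after a move of 1 kb, which argues against depth. Recovery of fragments that depends on GC content stays open, since the log2 ratio of replicate 1 over replicate 2 was 0.97 ± 0.19 (SD over 5 signal quintiles) higher in the GC-richest than in the GC-poorest quintile of shared distal peaks, but the weak peaks themselves had a median GC content of 52.5%, above the 46.5% of those in replicate 2 and below the 55.5% of stronger peaks in replicate 1. Cuts spread around strongly open regions also stay open, as 10.4% of the weak peaks lay within 5 kb of 1 of the strongest 10% of peaks against 5.48% in replicate 2, a ratio of 1.897 under the limit of 2 set for it, and peaks of middle signal lay there more often (12.98% and 14.1%), which goes against spread within 5 kb. No biological explanation was tested, since there is 1 group.

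Genes of ciliated cells were higher in replicate 2, at percentile 99.5 and a median log2 ratio of 0.34. The percentile was 99.5 with matching on GC and 99.2 after correcting each peak for GC. General recovery by GC content, as corrected here, therefore does not account for all of the difference. The correction of each peak lowered the median to 0.24, so a contribution of GC content stays open. For RFX sites, mismatches to the motif were allowed, and 340 shared distal peaks held an exact or near match. Exact matches were far fewer, so most of these were near matches. Their median log2 ratio was -0.04, at percentile 0.66 of matched peaks. That lies under the lower limit of -0.01 of the matched peaks, so distal peaks with such matches were not higher in replicate 2. Whether RFX factors use the near matches was not examined, so this cannot decide the use of distal RFX sites. Greater use of RFX sites at promoters also stays open, since promoter sites were not examined and the list itself was not higher on distal peaks. Scaling of promoter peaks stays open, since the list was at percentile 70.2 and a median of -0.27 without promoter peaks, which a difference at the promoters themselves would also give. On promoter peaks alone, with lists matched on promoter signal and GC, the median was 0.24 on 11 genes, as it was after the GC correction, and the call ended (percentile 92.9) because these random lists reached 0.33 at their upper limit against 0.18. More airway epithelium in the tissue of replicate 2 stays open, with airway secretory genes at percentile 71.7 on 12 genes that lean the same way (median log2 0.35), and the design has no group to test a biological explanation.

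Of the shared peaks, 96 differed by more than 8-fold after centring, 95 of them higher in replicate 2. Pairs were joined by an overlap of at least 1 bp, and whether both members covered the same segment was not examined. Nor was the GC content of these peaks, although GC-poor shared peaks were in general higher in replicate 2. The largest, chosen after their values were seen, were near Lrrc3c (11:98606891-98606980, 0.102 and 1.99), Pak3 (X:143482981-143483140, 2.31 and 40.9), Umodl1 (17:30950901-30951100, 0.162 and 2.66) and Kirrel (3:87090081-87090280, 0.242 and 3.63). Repeats might add to this, since 12.3% of their bases were soft-masked against 7.62% of all shared peaks, but the ratio of 1.62 lies between the limits set and leaves it open. Noise of weak peaks also stays open, as 21.9% of the 96 lay in the weakest quintile of mean signal and 1.04% in the strongest. Variants between the parental strains and the reference were not tested, since the files hold no sequence of the animals.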
